A study of Rattus norvegicus with 6 samples.

How the data were processed

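RNA sequencing was done on 6 libraries of cultured rat cells, 2 each of astrocytes, neurons and OPCs. Per the labels' protocols, total RNA was isolated with a column kit, 250 ng were sent for sequencing, and libraries made by a standard Illumina procedure were read on a HiSeq instrument. The deposited table gave raw counts per gene, whole numbers with a different total in each library. The aligner, the counting tool, the genome build and the annotation release are not given in the sources used here, nor is whether strand was used, so genes that overlap on opposite strands cannot be told apart. Columns were matched to samples by the description in the labels, and 0 columns of per-sample values were left out. No 2 libraries held identical counts. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

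Genes were listed by Ensembl rat identifiers. The table of gene names at hand (assembly GRCr8) was matched to them and paired 0 with a symbol, and the deposited table does not pair them either. Therefore 35 gene lists fixed before the data were examined, covering cell type markers and pathways, and the camera and fry tests planned on them were not run. The planned rule for named genes could be applied only without its requirement of a symbol and without its parts on gene lists. It took genes with an adjusted p under 0.05, a mean of at least 50 CPM in the higher group and both libraries of a group above both of the other, ordered by log2 fold change. At most 2 identifiers per direction are printed for each comparison.

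Tests used edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the cell type as group (minimum count 10, minimum total 15), which left 18206. Libraries were scaled by TMM factors between 0.794 and 1.21. A quasi-likelihood model with 1 coefficient per cell type was fitted to all 6 libraries with robust estimation, leaving 3 residual degrees of freedom, and each pair of cell types was compared by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. Standard errors of log2 fold changes were derived from the fold change and its F statistic. A gene was called enriched in a cell type when the larger of its 2 pairwise p-values, adjusted over all genes, was under 0.05 and its log2 fold change was above 1 against both others. Depleted genes, a class added after the data were seen, were defined the same way with the sign reversed. CPM values used the scaled library sizes. Distances are root mean square differences of log2 CPM with a prior count of 2. Where a gene had 0 counts in a group, its fold was computed against a floor of 3 counts over the group. With 1 to 3 counts, the pooled ratio is given with an exact 95% binomial interval of counting error. Of 17312 genes with a total of at least 100 counts, 102 had counts identical to those of another gene in all libraries, and genes with near-identical copies may share reads.

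The steps were tested on simulated data. Counts were drawn from each gene's mean over all 6 libraries, the real library sizes and the fitted dispersions. A gene had the same dispersion in every cell type, so the wider spread between the real neuron replicates was not simulated. In each run 200 genes were changed in a single cell type. Far fewer genes were changed than were called in the real data, so the recovery rates need not hold there. For neurons against astrocytes (17907 genes), 50 of 66 genes changed 8-fold, 12 of 67 changed 4-fold and 0 of 67 changed 2-fold were called with the right sign, with 6 false calls. For OPCs against astrocytes (17910 genes) the numbers were 46 of 66, 13 of 67 and 3 of 67, with 7 false calls. For neurons against OPCs (17926 genes) they were 42 of 66, 6 of 67 and 0 of 67, with 6 false calls. In each comparison the false calls were a larger share of the simulated calls than the adjusted p threshold of 0.05. The numbers of calls were small, so this share is imprecise. The pairwise calls in the real data may therefore hold more false calls than the threshold implies. Of 33 genes raised 8-fold in a single cell type, 18 were called enriched for astrocytes (17946 genes), 16 for neurons (17914 genes) and 22 for OPCs (17936 genes), with 0 false calls in each. Of 33 raised 4-fold, 2, 4 and 5 were called, and of 34 raised 2-fold, 0 in each. No gene was raised in 2 cell types at once, so false calls of such genes as enriched were not tested.

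The tests, the comparisons and most alternatives were fixed before the data were examined. The alternatives were RLE, upper-quartile and total-count scaling, DESeq2 1.42.0, limma-voom (limma 3.58.1), no low-count filter, a filter at a mean of 5 CPM, fits of 4 libraries, the replicate number as a block, a test against a log2 fold change of 1, omission of the 50 most abundant genes and omission of each library in turn on the same 18206 genes. Thinning all libraries to the smallest total, 22265917, and omitting each library with the low-count filter applied again were added after the data were seen.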

Results

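Messenger RNA of 3 kinds of rat neural cells grown in culture was profiled by RNA sequencing. Astrocytes are the star-shaped support cells of the brain, neurons its signalling cells, and oligodendrocyte precursor cells (OPCs) the dividing cells that give rise to myelin-forming oligodendrocytes. Each cell type was a separate commercial product and was represented by 2 libraries. The astrocytes and OPCs had been passaged 1 time, after 8 days in culture, and were grown for 6 more days. The neurons were not passaged and were grown for 7 days. Cell type therefore goes together with product, and for neurons also with passage and days in culture.

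Total counts were 102861667 and 50267809 for the astrocyte libraries, 75601751 and 55520161 for the neuron libraries, and 22265917 and 45077708 for the OPC libraries. The shallowest library was OPC replicate 1, where 3 counts correspond to a CPM, the count scaled to library size, of 0.135, against 0.0292 in astrocyte replicate 1. Both values use the total counts without TMM factors, unlike the other CPM values given here. Of 26405 genes in the table, 24873 had a count in at least 1 library and 18206 were tested. A CPM of at least 1 in all 6 libraries was reached by 12695 genes. The most abundant gene of a library took between 1.09% of counts in OPC replicate 2 (95% Wilson interval 1.085 to 1.091) and 2.55% in astrocyte replicate 1 (2.549 to 2.555). Such intervals and floors cover counting error only.

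The first question was how far the 3 cell types lay from one another beside the spread between replicates. The neuron and OPC libraries were the closest pair of cell types, at a root mean square log2 CPM difference of 1.74 ± 0.03 (SD over 4 pairs of libraries). Astrocyte libraries lay 2.46 ± 0.12 from neuron libraries and 2.38 ± 0.07 from OPC libraries, and the ranges of these distances, 2.34 to 2.61 and 2.29 to 2.44, overlapped. Replicates lay 0.79 apart for astrocytes, 1.17 for neurons and 0.77 for OPCs, so each pair of replicates was closer than any pair of libraries from different cell types. These distances share libraries, and no test was run on them. The rank correlation across genes was 0.862 between neuron and OPC libraries, 0.764 between astrocyte and OPC libraries and 0.716 between astrocyte and neuron libraries, where genes are not independent replicates. A principal component with 63.1% of the variance set the astrocyte libraries apart from the others, and a component with 24.6% parted neurons from OPCs.

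**Figure D1:**
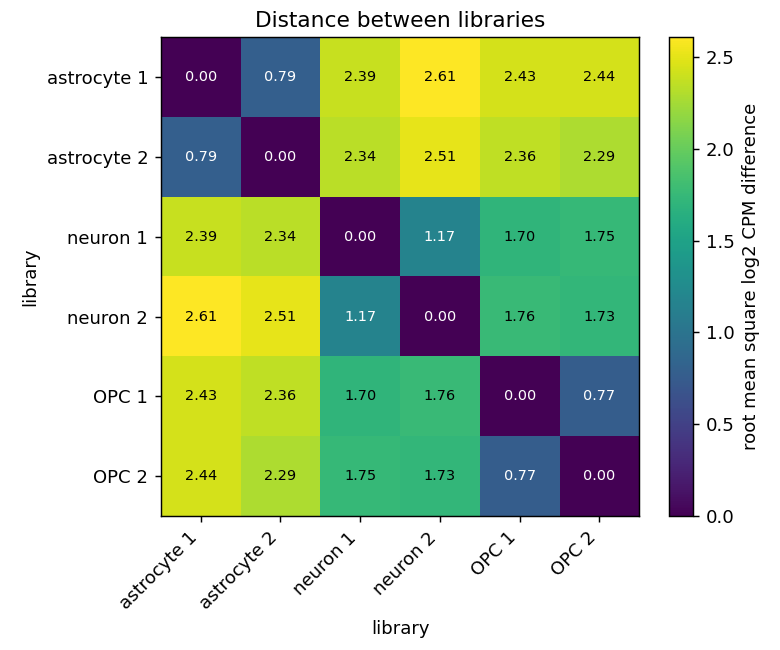
Root mean square log2 CPM difference between every pair of the 6 libraries, on a colour scale from 0, with the value in each cell. Neuron to OPC distances run from 1.70 to 1.76, below the distances of both cell types to the astrocyte libraries, which start at 2.29.

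In neurons 2639 genes were higher and 2893 lower than in astrocytes, together 5532 of the 18206 genes tested (30.4%). More than 8-fold differences made up 1454 of the higher and 1504 of the lower genes. Among the genes higher in neurons, ENSRNOG00000026055 stood at 288 ± 291 CPM (SD, n = 2; 82.0 and 494 in the replicates) and had 3 counts in all in the astrocyte libraries, all in replicate 1. The pooled ratio was 9952 (95% counting interval 3405 to 48263), with an edgeR adjusted p of 0.000909. ENSRNOG00000010834 stood at 288 ± 264 CPM in neurons and 0.0422 ± 0.0077 CPM in astrocytes (n = 2 each), a log2 fold change of 12.71 ± 1.11 (SE; edgeR adjusted p = 0.000551), which was 13.42 without neuron replicate 1 and 11.21 without neuron replicate 2. Among the genes lower in neurons, ENSRNOG00000012094 stood at 2404 ± 405 CPM in astrocytes and 0.852 ± 0.960 CPM in neurons, a log2 fold change of -11.43 ± 1.45 (SE; edgeR adjusted p = 0.00177), which was -13.74 without neuron replicate 1 and -10.61 without neuron replicate 2. ENSRNOG00000011821 stood at 341 ± 253 CPM in astrocytes and 0.113 ± 0.135 CPM in neurons, a log2 fold change of -11.41 ± 1.16 (SE; edgeR adjusted p = 0.000867). Its fold change was -10.33 without astrocyte replicate 2, -10.66 without neuron replicate 2 and -14.07 without neuron replicate 1, where 1 neuron count remained and the fitted value depends on the prior count. The number of genes called was 3306 without astrocyte replicate 1 and 3486 without astrocyte replicate 2. Scaling by total counts alone put 66.2% of the calls on the higher side in neurons, against 47.7% here, and moved the median log2 fold change of all genes from -0.06 to 0.40. Its 5945 calls included 4650 of the 5532.

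OPCs and astrocytes differed in 4649 genes (25.5% of those tested), with 1934 higher and 2715 lower in OPCs. More than 8-fold differences numbered 1735 among the lower genes and 942 among the higher genes. ENSRNOG00000025745 stood at 315 ± 321 CPM in OPCs (SD, n = 2; 542 and 87.8 in the replicates) and had 3 counts in all in the astrocyte libraries, all in replicate 2. Its pooled ratio was 10350 (95% counting interval 3541 to 50192; edgeR adjusted p = 0.0019). ENSRNOG00000009345 stood at 172 ± 92.5 CPM in OPCs and 0.0476 ± 0.0674 CPM in astrocytes, a log2 fold change of 12.17 ± 1.22 (SE; edgeR adjusted p = 0.000965). This was 10.90 without astrocyte replicate 1 and 11.46 without OPC replicate 1, and it was 16.37 without astrocyte replicate 2, where 0 astrocyte counts remained and the fitted value depends on the prior count. Of the genes that met the rule for naming, the deepest fall was that of ENSRNOG00000002548, at 21364 ± 15266 CPM in astrocytes (n = 2) and 0.526 ± 0.634 CPM in OPCs, a log2 fold change of -15.21 ± 2.59 (SE; edgeR adjusted p = 0.00628). The fold change was -14.09 without astrocyte replicate 1, -14.42 without OPC replicate 1 and -17.99 without OPC replicate 2, where 2 OPC counts remained. Without OPC replicate 1 its adjusted p was 0.0506, and over all alternatives the highest was 0.0581. ENSRNOG00000045829 stood at 8648 ± 7429 CPM in astrocytes and 0.463 ± 0.111 CPM in OPCs, a log2 fold change of -14.16 ± 1.55 (SE; edgeR adjusted p = 0.00126), which was -12.70 without astrocyte replicate 1 and -14.81 without astrocyte replicate 2. The number of genes called was 2645 without astrocyte replicate 1, 2276 without OPC replicate 1 and 2182 without OPC replicate 2. Total counts alone put 58.6% of the calls on the higher side in OPCs, against 41.6% here, with the median log2 fold change of all genes at 0.39 instead of -0.04. The 5067 calls with that scaling included 4033 of the 4649.

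Neurons and OPCs differed in 2260 genes (12.4% of those tested), with 1407 higher and 853 lower in neurons. The share of calls higher in neurons, 62.3%, was 53.7% without neuron replicate 1, 74.2% without neuron replicate 2 and 51.9% with the replicate block. More than 8-fold differences were found in 804 genes higher in neurons and 356 genes higher in OPCs. ENSRNOG00000049882 stood at 63.2 ± 72.6 CPM in neurons (SD, n = 2; 115 and 11.9 in the replicates) and had 0 counts in both OPC libraries (edgeR adjusted p = 0.0207). Against a floor of 3 counts over the OPC group, 0.0416 CPM, the neuron mean was at least 1522-fold higher, and neuron replicate 2 alone at least 286-fold. ENSRNOG00000026055, also among the genes higher in neurons than in astrocytes, had 1 count in the OPC libraries, a pooled ratio of 17436 (95% counting interval 3129 to 688700; edgeR adjusted p = 0.00419). ENSRNOG00000019031 stood at 88.9 ± 22.4 CPM in OPCs and 0.187 ± 0.0445 CPM in neurons, a log2 fold change of -8.85 ± 0.49 (SE; edgeR adjusted p = 0.00181). ENSRNOG00000025745 stood at 315 ± 321 CPM in OPCs and 0.919 ± 0.664 CPM in neurons, a log2 fold change of -8.40 ± 1.29 (SE; edgeR adjusted p = 0.012), which was -9.44 without neuron replicate 1, -6.56 without OPC replicate 1 and -9.20 without OPC replicate 2. The number of genes called was 225 without OPC replicate 1 and 116 without OPC replicate 2, and the cause was not tested. Without OPC replicate 1 the adjusted p was 0.0969 for ENSRNOG00000049882, 0.0509 for ENSRNOG00000026055 and 0.0524 for ENSRNOG00000025745, and without OPC replicate 2 it was 0.114 for ENSRNOG00000049882 and 0.0585 for ENSRNOG00000026055. With no low-count filter the edgeR adjusted p was 0.205 for ENSRNOG00000049882 and 0.059 for ENSRNOG00000025745.

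**Figure D2:**
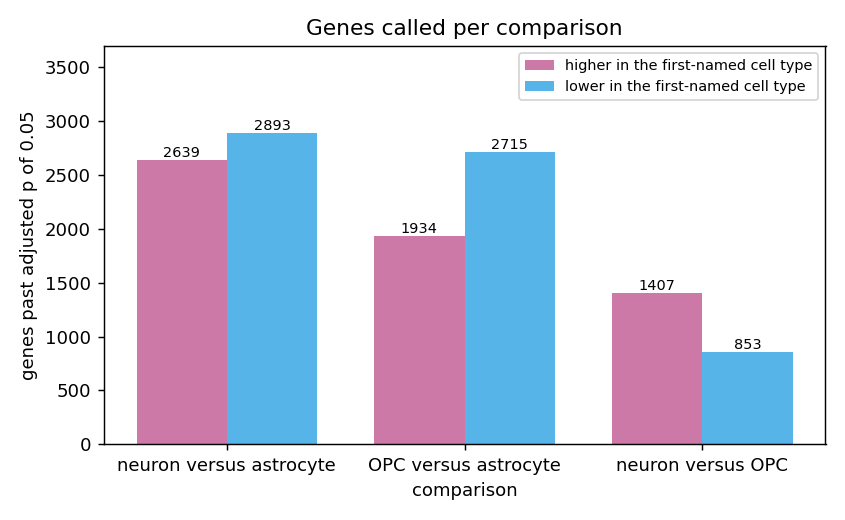
Number of genes past an edgeR adjusted p of 0.05 in each comparison, as bars from 0, split into genes higher and lower in the cell type named first. Neurons against astrocytes gave 2639 higher and 2893 lower genes, OPCs against astrocytes 1934 and 2715, and neurons against OPCs 1407 and 853.

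Genes enriched in a single cell type were most numerous in astrocytes. They passed a test of no difference against each of the others and had a fitted difference of more than 2-fold against both. Astrocytes had 1620 such genes, neurons 543 and OPCs 94. Of these, 1063, 363 and 64 were more than 8-fold higher than in both others. The astrocyte-enriched genes took 25.0 ± 3.96% of the counts in astrocyte libraries (SD, n = 2), 2.45 ± 0.56% in neuron libraries and 2.25 ± 0.02% in OPC libraries. The neuron-enriched genes took 4.68 ± 0.52% in neuron libraries, 0.562 ± 0.063% in OPC libraries and 0.214 ± 0.010% in astrocyte libraries. The OPC-enriched genes took 1.22 ± 0.23% in OPC libraries, 0.121 ± 0.025% in neuron libraries and 0.0709 ± 0.0020% in astrocyte libraries. Because the classes were selected on these libraries, the shares describe their size and are not independent evidence of their direction.

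The sizes of these classes moved with single libraries and with the replicate number as a block, which gave 307 neuron-enriched genes, 286 of them among the 543, and 1 OPC-enriched gene. With all libraries, 1560 neuron and 813 OPC genes had an unadjusted edgeR p under 0.05 and a log2 fold change above 1 against both others. The unadjusted counts below use the same rule. They changed far less than the adjusted counts when an OPC library was left out. No number expected by chance was worked out for this rule, so the unadjusted counts are not numbers of enriched genes. Astrocyte-enriched genes numbered 847 without astrocyte replicate 1, 1024 without astrocyte replicate 2, 826 without OPC replicate 1 and 716 without OPC replicate 2. Neuron-enriched genes numbered 290 and 306 without astrocyte replicates 1 and 2. Without either OPC library the edgeR test called 0 neuron-enriched genes, although 1287 and 1121 genes had an unadjusted p under 0.05 without OPC replicate 1 and 2. OPC-enriched genes numbered 20 without astrocyte replicate 1, 234 and 142 without neuron replicates 1 and 2, 1 without OPC replicate 1 and 0 without OPC replicate 2, where 649 genes had an unadjusted p under 0.05.

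**Figure D3:**
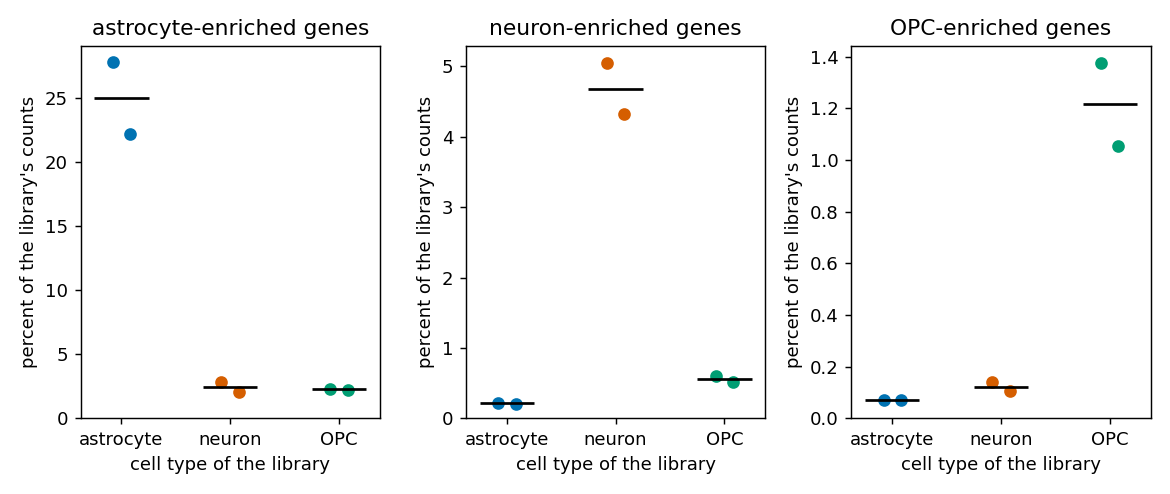
Percent of each library's counts taken by the genes enriched in astrocytes, neurons or OPCs, with a point per library and a line at the mean of the 2 libraries, on axes from 0 that differ in height. Astrocyte-enriched genes took 25.0% in astrocyte libraries, neuron-enriched genes 4.68% in neuron libraries and OPC-enriched genes 1.22% in OPC libraries.

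Replicates differed most in neurons. The SD of the log2 ratio of replicate 1 to replicate 2 was 1.15 in neurons, 0.79 in astrocytes and 0.77 in OPCs, and the biological coefficient of variation within the group was 52.2%, 34.4% and 30.1%. In neurons 453 genes were more than 8-fold higher in replicate 1 and 66 in replicate 2. The same counts were 28 and 60 in astrocytes, and 12 and 58 in OPCs. The fit of all 6 libraries shared its estimate of spread across cell types. That estimate can be too small for neurons and too large for the others. Fits of only the 4 libraries compared called 5898 genes for OPCs against astrocytes (4649 with all libraries). They called 4693 for neurons against astrocytes (5532) and 1987 for neurons against OPCs (2260). Whether the shared estimate caused these changes was not tested.

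**Figure D4:**
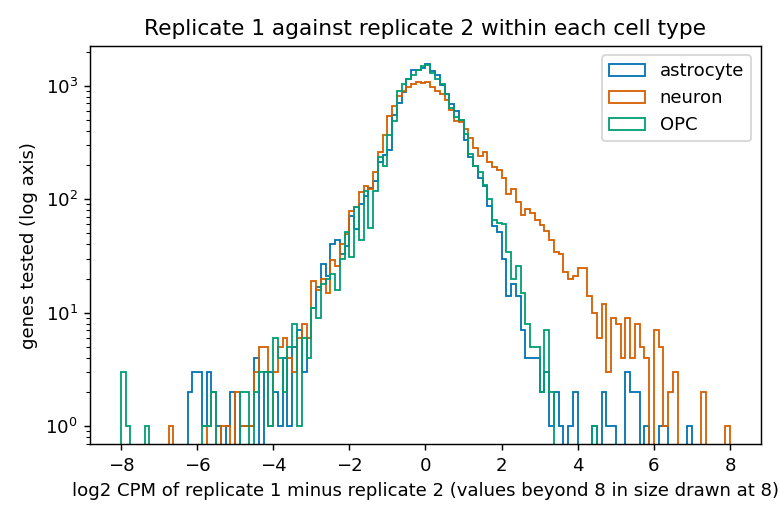
Distribution over the tested genes of the log2 CPM difference between replicate 1 and replicate 2 of each cell type, with the number of genes on a log axis. The neuron curve has a longer right side, with 453 genes more than 8-fold higher in replicate 1.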

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

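Thinning to the smallest total and leave-one-out with the filter applied again were chosen after seeing the data. Of 190 values of the named genes under alternatives, 181 stayed past the threshold in the same direction, 9 lost their call and 0 reversed. Because the named genes were picked in these same libraries for the largest fold changes, a reversal was hardly possible. Their kept direction is therefore no evidence of robustness. Other scalings kept the 3 comparisons within 1.5 times their counts, with partly other genes. DESeq2 called 4031 genes between neurons and OPCs (2260 by edgeR), 1244 neuron-enriched and 590 OPC-enriched genes, limma-voom 147 OPC-enriched genes, and a fit with no low-count filter 319. With a mean CPM of at least 5, fewer genes were tested and 1039 were astrocyte-enriched. Fits of only the 4 libraries compared gave 311 neuron-enriched genes. The stricter test against a log2 fold change of 1 gave 3637 genes for neurons against astrocytes and 1000 for neurons against OPCs. Except where stated, the cause was not tested.

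Leaving out 1 library in turn, where the lone library is assumed to vary like the other groups, gave 3283 to 5996 genes for neurons against astrocytes, 2108 to 5831 for OPCs against astrocytes and 116 to 2759 for neurons against OPCs. It gave 716 to 2034 astrocyte-enriched, 0 to 733 neuron-enriched and 0 to 234 OPC-enriched genes. The lowest counts came without astrocyte replicate 1 or an OPC library, and the highest without a neuron library. With 1 library left in a group, that group adds nothing to the estimate of spread, which then comes from the other pairs of replicates. The neuron pair varied most (biological coefficient of variation 52.2% against 34.4% in astrocytes and 30.1% in OPCs). It drops out where the counts were highest. Whether this accounts for the whole range was not tested.

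The replicate block gave 307 neuron-enriched genes (286 shared with the fit without it), 1 OPC-enriched gene (1 shared), 1505 astrocyte-enriched genes (1389 shared) and 6467, 4831 and 2445 genes in the pairwise comparisons. The correlation of deviations of libraries with the same number was 0.147 for astrocytes and neurons, 0.292 for astrocytes and OPCs and 0.162 for neurons and OPCs. With 2 numbers per cell type, and no label saying what a number marks, whether the numbers pair the libraries stays open.

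Distances for astrocyte to neuron, astrocyte to OPC and neuron to OPC were 2.59, 2.57 and 1.88 with a prior count of 0.5. As 1 minus the Spearman correlation, on another scale, they were 0.284, 0.236 and 0.138. For the last 2 pairs they were 2.29 and 1.61 at a mean CPM of at least 5 and 2.28 and 1.65 in thinned libraries. Neuron to OPC was 1.77 with total counts alone. Neuron to OPC was the shortest in each. Gene set alternatives were not run, since no gene list could be matched.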

Other observations

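The depleted classes and the genes seen in a single cell type were chosen after seeing the data, and the tests of astrocyte RNA as the whole cause and of both explanations of the replicate differences shared between cell types only after their results were seen.

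Genes depleted in a single cell type, lower than in both others, numbered 1003 in astrocytes, 168 in neurons and 159 in OPCs by the edgeR test. At an unadjusted p under 0.05, with the same fold change limit, they numbered 854 in neurons and 1049 in OPCs, again with no number expected by chance worked out. DESeq2 called 1535, 495 and 677, and limma-voom 901, 185 and 61. With no low-count filter there were 260 neuron-depleted and 366 OPC-depleted genes, with total counts alone 97 OPC-depleted genes, and in fits of only the 4 libraries compared 86 neuron-depleted genes. Total counts alone also reversed which astrocyte class was larger. It gave 1118 astrocyte-enriched and 1435 astrocyte-depleted genes, against 1620 and 1003 with TMM factors. Without astrocyte replicate 1 the edgeR counts were 543, 85 and 37, and without astrocyte replicate 2 they were 560, 96 and 104. Without neuron replicate 1 there were 629 neuron-depleted and 309 OPC-depleted genes, and without neuron replicate 2 there were 441 OPC-depleted genes. Astrocyte-depleted genes numbered 586 and 627 without OPC replicates 1 and 2, where edgeR called 0 neuron-depleted genes (703 and 574 at an unadjusted p under 0.05) and 0 OPC-depleted genes (757 and 655). The replicate block gave 0 OPC-depleted genes (973 at an unadjusted p under 0.05). The astrocyte-depleted genes took 0.483 ± 0.026% of counts in astrocyte libraries (SD, n = 2), 7.24 ± 0.78% in neuron libraries and 5.27 ± 0.74% in OPC libraries. Few genes passed a strict rule for being seen in a single cell type. With a CPM of at least 1 in both libraries of a cell type and at most 3 counts over the other 4 libraries, there were 10 genes in astrocytes, 18 in neurons and 0 in OPCs, out of 14610, 14254 and 14121 genes at that CPM. The limit of 3 counts is stricter where the other libraries are deeper, which holds most for OPCs. These numbers therefore depend on depth and do not rank the cell types.

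The 2 neuron libraries differed more than the replicates of the other groups. Sampling noise of genes with few reads is argued against, since in thinned libraries at a mean CPM of at least 10 the SD of the neuron log2 ratio was still 1.62 times the larger of the other SDs. Different shares of astrocyte RNA may contribute, as the 100 most astrocyte-specific genes had a median log2 ratio 1.57 ± 0.19 (bootstrap SE) above that of all genes. The bootstrap resampled genes within this pair of libraries, so its SE does not measure spread between libraries. No set of genes equally low in neurons was compared, so the value does not single out astrocyte RNA. The 100 genes took only 0.0441% and 0.0152% of neuron counts. Subtracting the astrocyte profile left the SD ratio at 1.76, against 1.64 before, which argues against astrocyte RNA as the whole cause. Values set to 0 by the subtraction can themselves widen the spread, which limits this. OPC RNA stays open. The OPC-specific genes used for it were picked by their fold change over astrocytes only. They took 1.13% and 0.926% of neuron counts against 2.22% of OPC counts, so neurons may express them too. Their excess of 0.78 ± 0.19 (SE from the same resampling of genes), between the bounds set for it, therefore cannot measure OPC RNA. No biological explanation was tested, as the labels give no difference between the replicates.

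The OPC libraries lay closer to the neuron than to the astrocyte libraries, with a ratio of mean distances of 0.729. Neuron RNA in the OPC libraries is argued against as the cause, because after subtracting the share that abundant neuron-specific genes allow, 1.14% and 1.21%, the ratio was 0.770. Subtracting an OPC share of 2.12% and 0.676% from the neuron libraries gave 0.762, which argues against OPC RNA there in the same way. A closer expression profile of the 2 cell types is a hypothesis that stays open, along with differences between the commercial products, which go together with cell type.

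Genes with a log2 ratio of replicate 1 to replicate 2 beyond 1 in size coincided between cell types, in 504 genes for astrocytes and neurons (308 if independent), 383 for astrocytes and OPCs (109 if independent) and 518 for neurons and OPCs (265 if independent), and genes with a wide spread in every cell type add to such an excess. The signs were the same in 71.4%, 91.6% and 70.7% of them, against 58.0%, 69.1% and 60.0% from the share of positive ratios in each cell type, while at a log2 ratio beyond 3 the sign was the same in 25 of 26 genes for astrocytes and neurons, 8 of 15 for astrocytes and OPCs and 10 of 18 for neurons and OPCs. Whether libraries with the same replicate number share a preparation was not tested and stays open, since no label says what a number marks. Replicate 1 was the deeper library in astrocytes and neurons but not in OPCs, so depth would make opposite signs prevail in the pairs with OPCs. For ratios beyond 1 this is argued against, as the lower percentage with OPCs was 70.7. For ratios beyond 3 the percentages with OPCs were 53.3 for astrocytes and 55.6 for neurons. The share of positive ratios alone gives 53.3 and 54.3, so depth stays open for these genes. Reads from 1 source common to all 19 genes over a log2 ratio of 3 in astrocytes and neurons are argued against. The astrocyte to neuron ratios of these genes had an SD of 1.93, against 2.39 over all genes. This SD cannot speak to smaller groups of near-identical genes among the 19, each with its own source. No biological explanation was tested.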
